A study of Mus musculus with 12 samples.

How the data were processed

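RNA was sequenced from fat that had been transplanted back into mice, collected 2 weeks after surgery. Before transplantation the fat had been kept without its blood supply for 0, 2, 4 or 8 h. The series title names necroptosis and the formation of oil cysts, which are pools of lipid left by dead adipocytes. The design text mentions storage on ice and at room temperature, and the labels do not give the temperature of each sample. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was purified with oligo(dT) beads, cDNA was primed with random hexamers, and the amplified double-stranded product was denatured and circularised with a splint oligonucleotide. No label mentions a step that keeps the strand, so reads from overlapping or antisense genes could not be told apart.

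The deposited gene table holds estimated counts (expected counts that need not be whole) for 19661 genes in 12 libraries, and 33.1% of its values are not whole numbers. The genome build is mm10, per the submitters' processing notes. The aligner and the counting program are not given in the sources used here. A deposited transcript table holds the same kind of estimated counts for 69283 transcripts in the 9 ischemia libraries. It was used only to check the gene table. In each of those 9 libraries at least 99.9% of genes had a transcript sum equal to the gene count within 0.05. The 0 h libraries could not be checked in this way. 1 deposited column holds an average of a group that is not among the samples, and it was not used. No mitochondrially encoded gene is in the gene table (0 genes), so the mitochondrial share was not assessed. Gene numbers of 19602 genes matched the RefSeq annotation of GRCm38, the assembly that mm10 denotes, and the coordinates are those of whole genes in that annotation.

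Samples were grouped by the hours of ischemia in their labels, with 3 libraries per group. The labels do not say whether replicates are separate animals, so p-values measure only the spread between these samples, which may be technical. Library totals ran from 18248188 to 20802437 estimated counts, and 16782 to 17218 genes had a count in a library. The 10 highest genes took 9.48% to 13.5% of the counts. Replicates of a group differed from each other by far more than sampling noise, so each library was counted as 1 sample. Reads amplified by PCR without molecular identifiers are not independent molecules, so floors and bounds cover counting error only.

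Estimated counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with trimmed mean of M-values (TMM) scaling, robust dispersion estimates and the filterByExpr filter (minimum count 10, minimum total 15). The filter left 14890 genes, and 699 genes were at 0 in all libraries. All 12 libraries entered 1 model of 4 groups, which share an estimate of the spread. Each duration was compared with 0 h and with each other duration, all 4 groups were tested together, and a slope over hours was fitted. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05, and all adjusted p-values of genes are from edgeR unless another tool is named. Standard errors of log2 fold changes are the fold change divided by the square root of its F value. Levels are CPM with TMM scaling, given as mean ± SD of 3 libraries.

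Lists of cell type markers and pathway genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01, adjusted over the 41 lists that had 5 or more tested genes. The same test with an estimated correlation, and the fry test, were run beside it. Fry asks whether the genes of a list move on balance to one side, and its mixed form whether they change in either direction. Neither compares the list with other genes. List medians are on the log2 CPM scale of limma and fold changes of single genes on the scale of edgeR. List medians with a gene at its bound, and those in the closing tests of explanations, are on the scale of edgeR. A list level in a library is the mean log2 CPM of its members minus their mean over the 12 libraries. Some lists share genes, so their results are not separate. S100a8 and S100a9 are in the neutrophil and the pattern recognition lists, and Tnfaip3 is in the NF-kappaB and the necroptosis lists. Tnf is in the necroptosis, the classically activated macrophage and the chemokine lists.

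The groups, the tests, the gene lists and the rule for naming genes were fixed before the data were examined, as were all alternatives except those named here. For each comparison with 0 h the rule took the 10 genes with the largest rise and the 10 with the largest fall among those passing the test, with a mean log2 CPM of at least 0 and no overlap between the libraries of the groups. Unnamed transcripts, pseudogenes and antigen receptor segments were passed over. Between durations it took 5 and 5, and for the test of 4 groups and the slope the 5 smallest p-values. Where no gene passed, it took the 3 with the smallest p-value. Necroptosis, adipocyte and macrophage genes were always named, and up to 4 members with the smallest p-value were named for each list described. The mean of the 3 ischemia groups against 0 h, its named genes, the fit without the 3 libraries highest in skeletal muscle genes, the fit with the level of those genes as a covariate, the list tests between durations with libraries left out, and the alternatives for Trib3, for Scn7a and for the mixed fry calls between 8 h and 4 h were chosen after seeing the data. The alternatives for Hdc were also chosen then.

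The other settings tried were size factors by relative log expression, no filter on low counts, a stricter filter (10 counts in every library of 2 groups), DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, only the 2 groups compared, ordinal steps for the slope, and leaving out each library in turn. The pipeline was tested on simulated counts for 14890 genes of the comparison of 2 h with 0 h. Of 50 genes each, changed by log2 1, 2, 3 and 6, it recovered 46%, 68%, 90% and 88%, and 2.01% of its 149 calls were false. With 50 genes changed by log2 6, 86% were recovered by the test of 4 groups. For the slope, 86% and 92% of 100 genes were recovered at log2 0.25 and 0.50 per hour. A simulated comparison of 8 h with 4 h without any change gave 0 calls. A neutrophil list lowered by log2 2 at 8 h had an estimated median of -1.96 and was called with the preset correlation (adjusted p = 7.01e-11) and with an estimated correlation (adjusted p = 0.00761), with 0 of 39 other lists called. Each gene was simulated independently. These results therefore do not measure error rates for genes that move together, as genes of the real libraries did, and least of all for the list tests.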

Results

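Poly(A) RNA was measured in grafted fat of mice at 2 weeks after autologous transplantation, in 4 groups of 3 libraries that differed in the ischemia of the fat before transplantation (0, 2, 4 or 8 h). Totals were similar across the groups, from 18248188 counts in 8 h replicate 2 to 20802437 in 2 h replicate 3. The most abundant transcript in each library was Col1a1 or Col3a1, which encode fibrillar collagens. The first principal component held 30.9% of the variance and placed the 0 h libraries between -49.1 and -38.7 and the 8 h libraries between 29.0 and 39.0. The 2 h libraries spread from -18.7 to 44.1, and in the 4 h group replicates 1 and 3 stood at -28.0 and -28.6 and replicate 2 at 41.3.

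Libraries of the same group differed in tissue makeup as measured by cell type markers. Skeletal muscle genes were high in 0 h replicate 2, 2 h replicate 2 and 4 h replicate 1, with list levels of 3.93, 4.71 and 3.51 on the log2 scale, and lower elsewhere (-2.29 to 1.30). Acta1 (Entrez 11459), the skeletal muscle actin, reached 154, 279 and 126 CPM in those 3 libraries. Markers of mature adipocytes also varied among the 0 h libraries, with list levels of -1.67, 1.24 and -2.18, and Adipoq (Entrez 11450), which encodes adiponectin, ran from 2.41 to 115 CPM there.

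The comparison of 2 h with 0 h asked what a short ischemia before transplantation changed in the graft. Neutrophil transcripts were far lower in the 2 h grafts. S100a8 (Entrez 20201, mm10 chromosome 3, 90669071 to 90670034), a subunit of calprotectin, stood at 155 ± 1.19 CPM (SD, n = 3) at 0 h and 1.54 ± 0.323 CPM at 2 h. Il1b (Entrez 16176, chromosome 2, 129364569 to 129371164), the inflammatory cytokine interleukin-1β, stood at 320 ± 190 and 2.60 ± 0.430 CPM. In the test, S100a8 fell by 6.65 ± 1.03 on the log2 scale (SE, adjusted p = 0.0234) and Il1b by 6.94 ± 0.86 (adjusted p = 0.0145). In total 149 genes fell and 24 rose among 14890 tested.

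Of the 11 tested genes in the neutrophil list, 4 fell over all genes tested (Csf3r, S100a8, Cxcr2 and S100a9) and 11 fell adjusted over the list alone. Csf3r, the receptor of granulocyte colony-stimulating factor, fell by 3.94 ± 0.53 and Cxcr2, a receptor of neutrophil-attracting chemokines, by 4.63 ± 0.77. The list median was -3.92, and on the scale of edgeR with Ly6g at its bound it was -3.56. Ly6g was at 0 in the 2 h libraries and at least 11.8-fold lower than at 0 h with a floor of 3 counts per library. Camera called the list lower (adjusted p = 2.62e-13), with adjusted p = 0.106 with an estimated correlation (9.08e-04 without 4 h replicate 2), and fry gave an adjusted p of 0.00171. The drop was seen beside muscle genes at both high and low levels, since the 0 h libraries had neutrophil list levels of 2.49 to 2.69 and muscle list levels of -2.29 to 3.93.

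Other genes with the largest fall included Acod1 (Entrez 16365, chromosome 14, 103047012 to 103056573), which makes itaconate in activated myeloid cells, from 189 ± 72.8 to 0.708 ± 0.151 CPM. Stfa2l1, Chil1, S100a9 and Cstdc4 fell by 7.76, 7.35, 7.13 and 6.86 on the log2 scale. Nlrp12, Mrgpra2a and Glycam1 also passed the test, with means of 0.0486, 0.0321 and 0.0481 CPM at 2 h against 7.87, 4.47 and 4.72 at 0 h, levels at 2 h that rest on 2 or 3 counts in all. Stfa2l1 and Cstdc4, and Mrgpra2a and Mrgpra2b, belong to families of near-identical genes, so the division of reads among members is uncertain.

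Genes of inflammatory mediators and targets of NF-κB were among those that fell. In the NF-kappaB feedback and adhesion list, 7 of 16 genes fell over all genes tested and 13 adjusted over the list alone, with 16 of 16 lower and a median of -1.34. Tnfaip3, Nfkb2, Nfkbie and Nfkbia, which limit or carry NF-κB signalling, fell by 1.81, 1.18, 1.66 and 1.29. Camera gave an adjusted p of 1.96e-13, with adjusted p = 0.106 with an estimated correlation, and fry 0.00171. Among chemokines and cytokines 7 of 26 fell over all genes and 11 adjusted over the list alone, among them Ccl3 by 4.05 ± 0.61, Csf3 by 6.36 ± 0.97 and Tnf by 2.65 ± 0.42. That list had an adjusted p of 1.04e-04 by camera and adjusted p = 0.428 with an estimated correlation.

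Pattern recognition and alarmin genes had 5 of 18 lower over all genes tested and 7 adjusted over the list alone, including Clec4e, a sensor of dead cells and mycobacteria, which fell by 3.40 ± 0.39, and Tlr2, which fell by 2.07 ± 0.34. Camera gave an adjusted p of 4.21e-04, with adjusted p = 0.401 with an estimated correlation. In the classically activated macrophage list 3 of 15 genes fell (Il1b, Fpr2 and Tnf) and 4 adjusted over the list alone (camera adjusted p = 1.38e-04). Its adjusted p was 0.228 with an estimated correlation. Of 6 lymph node stroma genes 1 fell, Glycam1, and 3 fell adjusted over the list alone with Ltb and Tnfsf11. That list had a camera adjusted p of 0.00332, adjusted p = 0.132 with an estimated correlation, and a fry adjusted p of 0.00241.

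Genes that rose at 2 h had varied roles. Car6 (Entrez 12353, chromosome 4, 150187015 to 150201135), a secreted carbonic anhydrase, rose from 0.921 ± 0.289 to 11.1 ± 6.61 CPM (log2 3.58 ± 0.65, adjusted p = 0.0350). Slc6a7 (Entrez 240332, chromosome 18, 60995376 to 61014416), a proline transporter, rose from 2.60 ± 1.33 to 17.1 ± 1.62 CPM. Pdk4, which restrains glucose oxidation, and Txnip, which binds thioredoxin, rose by log2 1.97 and 1.31. Megf10, an engulfment receptor, rose by 3.44, Col4a5, a basement membrane collagen, by 2.32, and Enpp5, Scn7a, Wee1 and Mpp6 by 1.36, 1.29, 1.24 and 1.21. Of 8 erythroid and haemoglobin genes 0 rose over all genes tested by edgeR (5 at an unadjusted p under 0.05, 5 by DESeq2 and 3 by limma-voom), and 5 rose adjusted over the list alone, with a median of 2.14. Camera gave this list an adjusted p of 7.27e-04 and adjusted p = 0.615 with an estimated correlation.

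The count of 173 genes at 2 h was 10, 556 and 12 without 0 h replicates 1, 2 and 3, 56, 19 and 0 without 2 h replicates 1, 2 and 3, 69 without 4 h replicate 1, and 82, 66 and 45 without 8 h replicates 1, 2 and 3. It was 33 with the 2 groups alone, 1033 by DESeq2 and 2274 by limma-voom, and of the 20 named genes 0 passed without 0 h replicate 1 or 2 h replicate 3. Over 21 other settings the log2 values of Il1b and S100a8 at 2 h ran from -7.47 to -6.59 and from -6.79 to -6.50. The call was lost in 3 of them for Il1b, 8 for S100a8 and Slc6a7, 13 for Car6 and 17 for Pdk4.

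**Figure D1:**
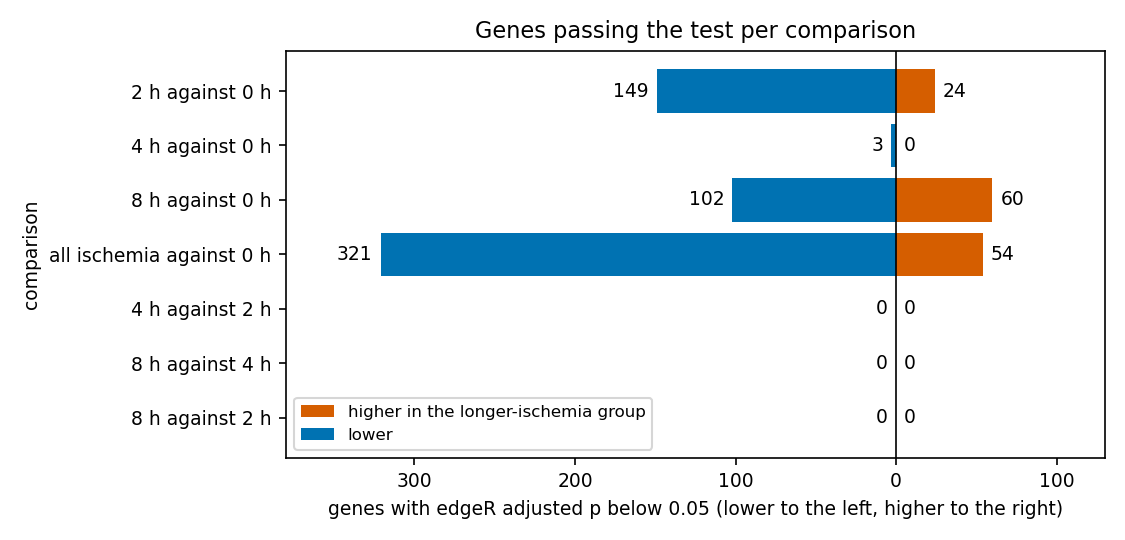
Genes passing the edgeR test (adjusted p below 0.05) in each comparison, lower genes to the left and higher genes to the right of 0. The mean of the ischemia groups had 321 lower and 54 higher genes against 0 h, and the 3 comparisons between durations had 0.

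The comparison of 4 h with 0 h gave 3 genes, all lower. Nlrp3 (Entrez 216799, chromosome 11, 59541569 to 59566955), the sensor of the NLRP3 inflammasome, fell from 50.3 ± 20.1 to 10.8 ± 0.837 CPM (log2 -2.21 ± 0.26, adjusted p = 0.0397). Rab11fip1 (Entrez 75767, chromosome 8, 27138773 to 27174646), which acts in endosome recycling, fell by 1.75 ± 0.19 (adjusted p = 0.0356). Dgat1 (Entrez 13350, chromosome 15, 76502012 to 76512021), which makes triglyceride from diacylglycerol, fell by 0.99 ± 0.12 (adjusted p = 0.0397), from 41.4 ± 5.35 to 20.8 ± 0.246 CPM. These genes also fell at 2 h and at 8 h.

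Neutrophil genes split the 4 h group. Replicates 1 and 3 had S100a8 at 38.0 and 36.0 CPM and neutrophil list levels of 0.90 and 0.89, and replicate 2 had 0.937 CPM and -1.80. Over the group 0 of 11 neutrophil genes fell over all genes tested by edgeR (8 at an unadjusted p under 0.05, 3 by DESeq2 and 3 by limma-voom) and 8 adjusted over the list alone, with a median of -2.32. Camera gave an adjusted p of 1.43e-11, with adjusted p = 0.103 with an estimated correlation (0.00311 without 4 h replicate 2), and fry 0.0183. NF-kappaB feedback and adhesion genes had 0 of 16 passing over all genes by edgeR (12 at an unadjusted p under 0.05, 6 by DESeq2 and 6 by limma-voom) and 10 lower adjusted over the list alone (Tnfaip3, Icam1, Sod2 and Nfkbia had the smallest p-values). Their median was -0.80, with a camera adjusted p of 1.43e-11 and adjusted p = 0.103 with an estimated correlation.

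T cell genes had 0 of 15 passing over all genes by edgeR (7 at an unadjusted p under 0.05, 4 by DESeq2 and 2 by limma-voom) and 5 lower adjusted over the list alone at 4 h, with 14 of 15 lower (camera adjusted p = 2.69e-08). The adjusted p of the T cell list was 0.314 with an estimated correlation. Ctla4, Cd6, Icos and Cd3g had log2 values of -2.22, -1.72, -1.65 and -2.59. Erythroid and haemoglobin genes had 0 of 8 passing over all genes by edgeR (7 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma-voom) and 7 higher adjusted over the list alone, with Alas2 at 3.02 ± 0.69 and Hba-a2 at 3.84 ± 0.89. For them camera gave an adjusted p of 2.55e-08, with adjusted p = 0.268 with an estimated correlation.

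At an unadjusted p under 0.05, 1315 genes differed between 4 h and 0 h, and DESeq2 and limma-voom called 292 and 210. The count of 3 became 0, 54 and 1 without 0 h replicates 1, 2 and 3, 13, 14 and 0 without 2 h replicates 1, 2 and 3, 0 without 4 h replicate 1 or replicate 3, 0 without 8 h replicate 1 or replicate 3, 0 with the 2 groups alone, and 12 with the skeletal muscle covariate. Nlrp3, Rab11fip1 and Dgat1 lost the call in 12, 9 and 13 of 21 other settings.

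The comparison of 8 h with 0 h covered the longest ischemia. 102 genes fell and 60 rose. S100a8 and Il1b were again low: S100a8 stood at 2.54 ± 0.222 CPM and Il1b at 2.22 ± 1.47 CPM, and they fell by 5.93 ± 0.99 (adjusted p = 0.0322) and 7.17 ± 0.88 (adjusted p = 0.0225). Among the genes that rose were 5 that encode interferon-inducible GTPases. Gbp2 (Entrez 14469, chromosome 3, 142620663 to 142638008), a guanylate-binding protein, rose from 43.8 ± 4.10 to 579 ± 276 CPM (log2 3.72 ± 0.47, adjusted p = 0.0225), and Iigp1 (Entrez 60440, chromosome 18, 60373616 to 60392634) from 34.5 ± 1.85 to 573 ± 375 CPM (log2 4.06 ± 0.64, adjusted p = 0.0316).

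Of 18 interferon response genes 1 rose over all genes tested, Gbp2, and 6 rose adjusted over the list alone, among them Gbp3 (log2 2.61 ± 0.54), Ifi47 (2.58 ± 0.66) and Ifit2 (2.62 ± 0.75). 18 of 18 were higher, with a median of 1.76. Camera called the list higher (adjusted p = 3.00e-08), with adjusted p = 0.580 with an estimated correlation, and fry gave 0.169. The list level was 1.69, 0.20 and 0.93 in the 8 h libraries and -0.96, 1.72 and 0.35 in the 2 h libraries. High levels were thus not limited to 8 h. At 2 h against 0 h 0 of the 18 passed over all genes by edgeR (9 at an unadjusted p under 0.05, 4 by DESeq2 and 1 by limma-voom). Outside the list Igtp, Gbp8 and Gbp2b rose by log2 3.68, 3.92 and 8.15. Gbp2b reached 84.4, 5.60 and 17.5 CPM in the 3 libraries at 8 h against 0.122 ± 0.0842 CPM at 0 h, and its sequence is close to that of Gbp2, so reads may be split between them. C6, a component of the complement membrane attack complex, rose from 2.20 ± 0.886 to 42.4 ± 33.7 CPM.

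Of the 11 neutrophil genes 5 fell at 8 h over all genes tested and 10 adjusted over the list alone, with a median of -3.83. On the scale of edgeR the median was -3.50 with Ly6g at its bound of at least 10.5-fold lower. Camera gave an adjusted p of 2.36e-10, with adjusted p = 0.381 with an estimated correlation (0.00163 without 4 h replicate 2), and fry 0.00556. Slpi, an inhibitor of neutrophil proteases, fell by 5.90 ± 0.92, and Stfa2l1, Cstdc4, S100a9 and Chil1 fell by 6.98, 6.71, 6.60 and 6.15. Mrgpra2b was at 0 in the 8 h libraries and at least 75.0-fold lower than its 12.2 ± 5.61 CPM at 0 h, with a floor of 3 counts per library. Mrgpra2a and Glycam1 fell to 0.0556 and 0.0352 CPM, which again rest on 2 or 3 counts. NF-kappaB feedback and adhesion genes had 2 of 16 lower over all genes (Tnfaip3 and Nfkb2) and 11 adjusted over the list alone, with a camera adjusted p of 5.20e-08, adjusted p = 0.416 with an estimated correlation and a fry adjusted p of 0.0127.

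Erythroid and haemoglobin genes were higher in 8 of 8 at 8 h. 1 rose over all genes tested, Alas2, the erythroid enzyme of haem synthesis, by log2 3.72 ± 0.70, and 7 rose adjusted over the list alone. Hba-a2 and Hbb-bt stood at log2 4.28 ± 0.91 and 3.94 ± 0.82, and the copies of each haemoglobin gene share reads. The list had a median of 3.74 and a camera adjusted p of 4.06e-08, with adjusted p = 0.491 with an estimated correlation and 0.0284 by fry. Car6, Megf10 and Tmem200a rose by log2 3.61, 3.45 and 3.31.

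Alternatively activated and resident macrophage genes had 0 of 16 passing over all genes by edgeR (7 at an unadjusted p under 0.05, 6 by DESeq2 and 7 by limma-voom) and 6 higher adjusted over the list alone at 8 h. Cd163, a haemoglobin scavenger receptor, stood at log2 2.65 ± 0.56, Clec10a at 2.87 ± 0.63, Folr2 at 1.51 ± 0.40 and Lyve1 at 3.33 ± 0.91. The list had a camera adjusted p of 1.38e-05, with adjusted p = 0.491 with an estimated correlation. Hypoxia response genes were higher in 18 of 18, with 0 passing by edgeR over all genes or adjusted over the list alone (10 at an unadjusted p under 0.05, 6 by DESeq2 and 10 by limma-voom), a median of 1.10 and a camera adjusted p of 3.33e-07. The adjusted p of the hypoxia list was 0.580 with an estimated correlation. Its level was 0.79, 0.81 and 0.80 in the 8 h libraries and 1.17, -1.24 and 0.12 in the 2 h libraries. Natural killer and cytotoxic cell genes were higher in 11 of 11, with 0 passing over all genes by edgeR (5 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom) and 3 adjusted over the list alone. These were Gzma, Prf1 and Ncr1, at log2 3.04, 2.42 and 1.81, and the list had a camera adjusted p of 0.00113 and adjusted p = 0.661 with an estimated correlation. The natural killer list level was 1.76, -0.09 and 0.90 in the 8 h libraries and -1.09, 1.06 and 0.41 in the 2 h libraries.

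At 8 h the chemokines and cytokines list had 5 of 26 lower over all genes and 8 lower and 3 higher adjusted over the list alone, with a median of 0.01 and a mean of -0.78. Its camera test did not pass (adjusted p = 0.398, lower). Ccl3, Cxcl2 and Cxcl5 fell by 4.00, 3.87 and 5.31. Ccl8 and Cxcl9 stood at log2 2.60 ± 0.53 and 3.65 ± 0.75 (adjusted p = 0.0520 and 0.0532).

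The count of 162 at 8 h was 3, 390 and 2 without 0 h replicates 1, 2 and 3, 386, 251 and 6 without 2 h replicates 1, 2 and 3, 5 and 374 without 4 h replicates 1 and 2, and 0, 19 and 2 without 8 h replicates 1, 2 and 3. It was 1254 by DESeq2, 2561 by limma-voom, 551 with the 2 groups alone, 299 without the 3 libraries highest in skeletal muscle genes and 306 with the muscle covariate, and of the 20 named genes 0 passed without 0 h replicate 1, 0 h replicate 3, 2 h replicate 3, 4 h replicate 1, 8 h replicate 1 or 8 h replicate 3. Over 21 other settings the log2 values of Il1b and Gbp2 at 8 h ran from -7.61 to -6.71 and from 3.43 to 4.07. The call was lost in 7 of them for each of these genes, 9 for S100a8, 10 for Alas2 and 11 for Tmem200a.

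**Figure D2:**
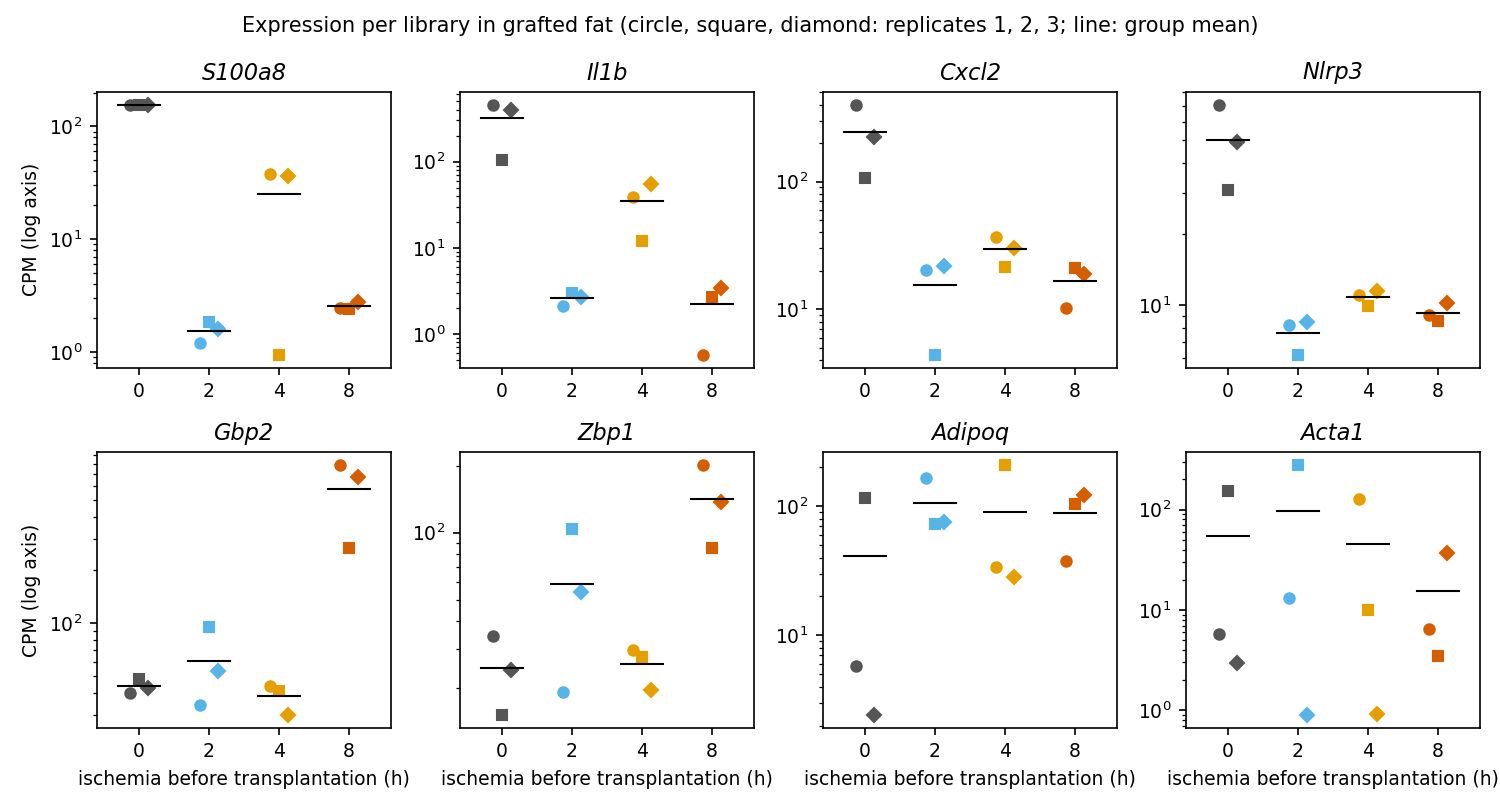
CPM of 8 genes in each library (log axis), with symbols for replicates and a line at the group mean. S100a8 lies between 154 and 157 CPM at 0 h and between 0.937 and 38.0 CPM after ischemia, Gbp2 is highest at 8 h (267 to 792 CPM), and Adipoq and Acta1 vary widely within groups.

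The mean of the 3 ischemia groups against 0 h, a comparison added after seeing the data, gave 321 genes lower and 54 higher. Of the neutrophil genes 8 of 11 fell over all genes tested and 11 adjusted over the list alone, and of the NF-kappaB feedback and adhesion genes 8 of 16 fell and 14 adjusted over the list alone. Il1b fell by 5.76 ± 0.52 (adjusted p = 0.00121), S100a8 by 5.07 ± 0.61 (adjusted p = 0.00377), and Stfa2l1, Chil1, Cstdc4, S100a9 and Acod1 by 6.05, 5.99, 5.69, 5.49 and 5.42. Slc6a7 rose by log2 2.78 ± 0.39 (adjusted p = 0.00712), and it passed in 20 of 20 other settings, with an adjusted p between 1.85e-12 and 0.0479.

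Mrgpra2b, Mrgpra2a and Glycam1 also fell in the pooled comparison (adjusted p = 0.00986, 0.00364 and 0.00630). Mrgpra2b stood at 12.2 CPM at 0 h and at 0.0627, 1.49 and 0 CPM at 2, 4 and 8 h, Mrgpra2a at 4.47 against 0.0321, 0.0930 and 0.0556 CPM, and Glycam1 at 4.72 against 0.0481, 0.279 and 0.0352 CPM. Erythroid genes Hba-a2, Hbb-bt and Alas2 rose by log2 3.65, 3.31 and 2.99, and of 8 erythroid and haemoglobin genes 3 rose over all genes and 7 adjusted over the list alone. Megf10, Car6 and Tmem200a rose by 3.41, 3.20 and 2.82, and Fcna, a ficolin of resident macrophages, Pdk4 and Glrp1 by 2.10, 1.91 and 1.33. Hba-a2, Hbb-bt and Alas2 lost the call in 15, 14 and 13 of 20 other settings, among them each single library left out except 2 h replicate 2 and 4 h replicate 3, with an adjusted p of up to 0.207, 0.196 and 0.166. Fcna, Tmem200a, Glrp1, Car6, Megf10 and Pdk4 lost it in 12, 10, 9, 8, 3 and 2 of 20 (adjusted p up to 0.179, 0.161, 0.119, 0.131, 0.109 and 0.128). Of the named genes that fell, Mrgpra2b lost it in 1 of 19, without 0 h replicate 1 (0.0582), and each of the others in 0.

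For the neutrophil, NF-kappaB feedback and adhesion, and erythroid and haemoglobin lists camera gave adjusted p = 3.68e-13, 1.45e-12 and 1.95e-07. The adjusted p of these lists was 0.124, 0.124 and 0.385 with an estimated correlation, and 7.80e-04 for the neutrophil list without 4 h replicate 2.

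The pooled count of 375 was 75, 619 and 121 without 0 h replicates 1, 2 and 3, 218 without 2 h replicate 3, 208 without 4 h replicate 1, and 204, 184 and 199 without 8 h replicates 1, 2 and 3. It was 1183 by DESeq2 and 1711 by limma-voom.

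**Figure D3:**
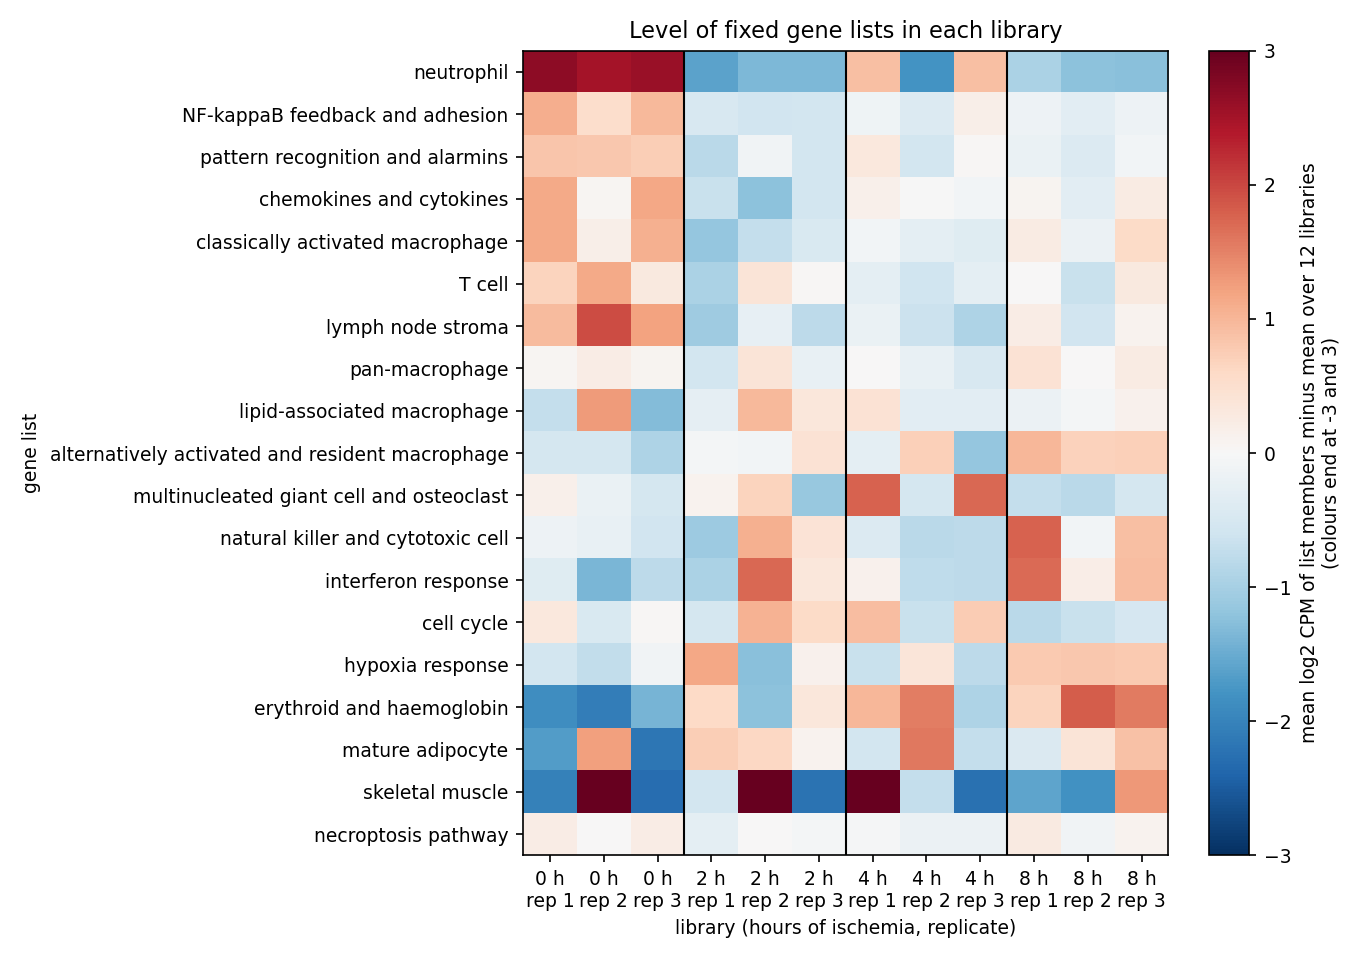
Level of 19 gene lists in each of the 12 libraries, as mean log2 CPM of list members minus the mean over all libraries, with colours ending at -3 and 3. The neutrophil list lies at 2.49 to 2.69 in the 0 h libraries and at 0.90, -1.80 and 0.89 in the 4 h libraries, and the skeletal muscle list stands out in 0 h replicate 2, 2 h replicate 2 and 4 h replicate 1.

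Genes of necroptosis, the regulated necrosis named in the series title, were examined in each comparison. Ripk1 (Entrez 19766, chromosome 13, 34002225 to 34035170) and Ripk3 (Entrez 56532, chromosome 14, 55784995 to 55788857), the kinases of the necrosome, and Casp8, the protease that restrains it, had log2 values between -0.08 and 0.25 in all comparisons with 0 h, and 0 of their tests passed by edgeR, DESeq2 or limma-voom (Ripk1 at 8 h had an unadjusted p of 0.0447). Mlkl (Entrez 74568, chromosome 8, 111311255 to 111338479), the executioner, stood at 25.8 ± 6.12 CPM at 0 h and 53.4 ± 14.2 CPM at 8 h (log2 1.05 ± 0.22, adjusted p = 0.0532), short of the threshold. Zbp1 (Entrez 58203, chromosome 2, 173206612 to 173218959), a sensor that activates RIPK3 and is induced by interferon, stood at 24.4 ± 9.54 and 142 ± 58.7 CPM (log2 2.53 ± 0.57, adjusted p = 0.0614).

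Mlkl at 8 h passed in 8 of 21 other settings: without 0 h replicate 2 (adjusted p = 0.0325), 2 h replicate 1 (0.0434), 2 h replicate 2 (0.0498) or 4 h replicate 2 (0.0487), without the 3 libraries highest in muscle genes (0.0486), with the muscle covariate (0.0341), by DESeq2 (3.94e-04) and by limma-voom (0.00663), and its adjusted p ranged up to 0.193. Zbp1 passed in 5 of 21: without 2 h replicate 1 (0.0311) or 2 h replicate 2 (0.0395), with the 2 groups alone (0.0359), by DESeq2 (1.97e-04) and by limma-voom (0.00745), with an adjusted p of up to 0.224.

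In the necroptosis pathway list 3 of 22 genes fell at 2 h over all genes tested (Tnfaip3, Tnf and Birc3) and 7 adjusted over the list alone, with Fas at log2 -1.42 ± 0.30. The list had a median of -0.06, and camera called it lower (adjusted p = 0.0361, and adjusted p = 0.657 with an estimated correlation), a call lost without 2 h replicate 1 (0.384) or 8 h replicate 1 (0.0516). At 4 h 0 passed over all genes by edgeR (5 at an unadjusted p under 0.05, 4 by DESeq2 and 4 by limma-voom) and 5 fell adjusted over the list alone (camera adjusted p = 0.0130, lost without 4 h replicate 3 at 0.0628). Its adjusted p at 4 h was 0.533 with an estimated correlation. At 8 h 2 fell over all genes, Tnfaip3 and Tnf, and 7 fell and 3 rose adjusted over the list alone, the latter Mlkl, Zbp1 and Tlr4, with a median of 0.00, a mean of -0.06 and a camera adjusted p of 0.703. The mixed fry test, which counts change in either direction, gave adjusted p = 8.53e-05 at 2 h, 0.00150 at 4 h and 6.73e-05 at 8 h.

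Among pyroptosis and inflammasome genes 2 of 16 fell at 2 h (Nlrp3 and Il1b) and 3 adjusted over the list alone with Il1a. Camera called this list lower (adjusted p = 0.0117, 0.384 without 2 h replicate 1), with adjusted p = 0.615 with an estimated correlation. At 4 h 1 fell, Nlrp3, and 3 adjusted over the list alone (camera adjusted p = 1.72e-05, and adjusted p = 0.185 with an estimated correlation). At 8 h 2 fell and 4 adjusted over the list alone. The median at 8 h was 0.11 while the mean was -0.80 and the camera test leaned lower (adjusted p = 0.444). In the apoptosis pathway 0 of 20 genes passed by edgeR in the comparisons with 0 h, and adjusted over the list alone 0, 0 and 2 passed at 2, 4 and 8 h, namely Bcl2l11 (log2 -0.77) and Bcl2 (0.77). At 2, 4 and 8 h 4, 2 and 6 apoptosis genes had an unadjusted p under 0.05, and DESeq2 called 0, 1 and 4 and limma-voom 5, 0 and 6. Of 18 ferroptosis and iron handling genes 0 passed by edgeR over all genes, and 5 passed adjusted over the list alone at 8 h, with Acsl4 and Aifm2 at log2 0.66 and 1.00 and Tfrc and Slc7a11 at -1.81 and -2.29. For that list 4, 1 and 6 had an unadjusted p under 0.05 at 2, 4 and 8 h, and DESeq2 called 1, 0 and 5 and limma-voom 2, 0 and 7. Camera gave the ferroptosis and iron handling list adjusted p = 0.403 at 8 h, and 0.0224 (higher) without 0 h replicate 2 and 0.0190 (higher) without the 3 libraries highest in skeletal muscle genes. The adjusted p in these fits was 0.330 and 0.585 with an estimated correlation.

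**Figure D4:**
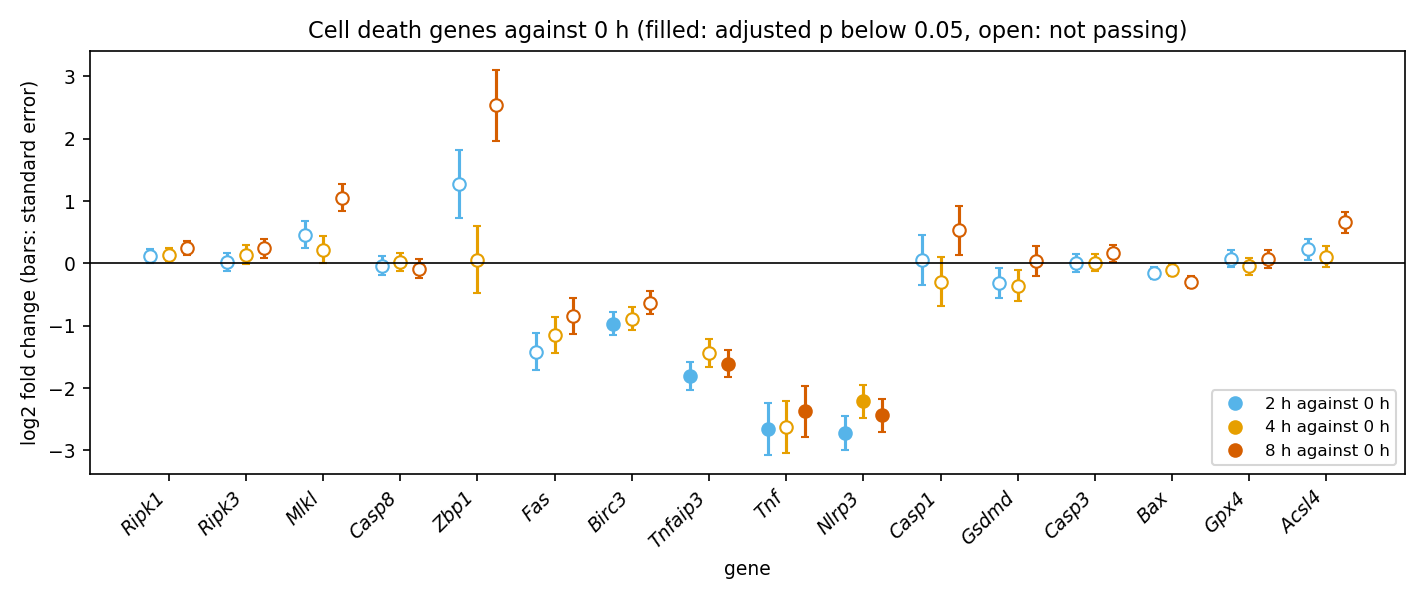
Log2 fold change against 0 h for 16 cell death genes at 2, 4 and 8 h, with standard errors as bars, filled points where the edgeR adjusted p is below 0.05. Nlrp3 is filled at each duration (-2.72, -2.21 and -2.44), Ripk1, Ripk3 and Casp8 lie near 0, and Mlkl and Zbp1 at 8 h are open at 1.05 and 2.53.

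Adipocyte genes spread widely within the 0 h group. The mature adipocyte level was -1.67 and -2.18 in 0 h replicates 1 and 3, below the range of the 9 ischemia libraries (-0.72 to 1.59), and 1.24 in 0 h replicate 2. Adipoq stood at 41.2 ± 64.2 CPM at 0 h and at 105 ± 53.1, 90.1 ± 102 and 87.8 ± 44.2 CPM at 2, 4 and 8 h. Plin1, the perilipin of lipid droplets, stood at 28.5 ± 32.1, 64.9 ± 52.8, 49.6 ± 48.5 and 61.1 ± 12.9 CPM. For Adipoq, Plin1, Lep and Fabp4 the adjusted p at 2 h was 0.629, 0.545, 0.627 and 0.356, and 0 of 24 mature adipocyte genes passed over all genes by edgeR, or adjusted over the list alone, at 2, 4 or 8 h. An unadjusted p under 0.05 was seen for 0, 0 and 1 of the 24, DESeq2 called 0 at each duration, and limma-voom called 9, 0 and 14. Over 21 other settings the log2 value of Adipoq ran from 0.79 to 4.88 at 2 h, from -0.41 (without 4 h replicate 2) to 4.86 at 4 h and from 0.54 to 4.42 at 8 h. Without 0 h replicate 2 it was 4.67, 4.46 and 4.42 (adjusted p = 0.0587, 0.151 and 0.0704). By limma-voom Adipoq passed at 2 h (log2 3.84, adjusted p = 0.0295) and at 8 h (log2 4.01, adjusted p = 0.0221), and Plin1 at 8 h (log2 2.38, adjusted p = 0.0206). The adjusted p of Adipoq reached 0.836 at 2 h and 0.873 at 8 h, and that of Plin1 0.786 at 8 h.

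The mature adipocyte list had medians of 1.30, 0.92 and 1.16 at 2, 4 and 8 h, with camera adjusted p = 2.19e-04, 8.01e-04 and 0.00164. Its adjusted p was 0.718, 0.651 and 0.904 with an estimated correlation. Without 0 h replicate 2 the medians were 2.25, 1.89 and 2.04 (camera adjusted p = 1.31e-10, 3.06e-12 and 5.68e-09), and without the 3 libraries highest in skeletal muscle genes 2.18, 2.16 and 2.04 (4.24e-09, 5.78e-13 and 5.22e-08). The adjusted p was 0.688, 0.462 and 0.704, and 0.561, 0.4997 and 0.585, with an estimated correlation. The camera call of the mature adipocyte list at 4 h was lost without 0 h replicate 1 (0.0682, median 0.54), 0 h replicate 3 (0.184, median 0.46) or 4 h replicate 2 (0.504, median 0.31), and at 8 h without 0 h replicate 3 (0.128, median 0.62). Fabp4 passed without 0 h replicate 2, the control high in muscle and adipocyte genes and in Fabp4 itself (1148 CPM against 280 and 224 in replicates 1 and 3), at 2 h (log2 2.30, adjusted p = 0.0256) and at 8 h (log2 2.09, adjusted p = 0.0391), and also by limma-voom. Over 21 other settings its adjusted p ran from 0.0153 to 0.621 at 2 h and from 0.00739 to 0.690 at 8 h.

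Adgre1, which encodes the macrophage marker F4/80, stood at 244 ± 12.4, 292 ± 164, 200 ± 88.3 and 241 ± 48.6 CPM at 0, 2, 4 and 8 h, and Cd68 at 582 ± 352, 868 ± 481, 675 ± 233 and 586 ± 55.9 CPM. Trem2 and Gpnmb, genes of lipid-laden macrophages, had log2 values of 0.61 ± 0.56 and 0.66 ± 0.98 at 2 h and 0.23 ± 0.56 and -0.68 ± 0.98 at 8 h. Gpnmb stood at 4480 CPM in 0 h replicate 2 and at 539 and 223 CPM in 0 h replicates 1 and 3, and without replicate 2 the log2 values were 1.62 and 2.86 at 2 h and 1.26 and 1.53 at 8 h, none of them passing (adjusted p = 0.0667, 0.0847, 0.122 and 0.261). By limma-voom Trem2 passed at 2 h (log2 1.33, adjusted p = 0.0295) and at 8 h (log2 1.09, adjusted p = 0.0428) and Gpnmb at 2 h (log2 2.32, adjusted p = 0.0390). Over 21 other settings the adjusted p of Trem2 ran from 0.0295 to 0.941 at 2 h and from 0.0428 to 0.967 at 8 h, and that of Gpnmb from 0.0390 to 0.976 and from 0.116 to 0.985. Of 19 lipid-associated macrophage genes 0 passed over all genes by edgeR, or adjusted over the list alone, in the comparisons with 0 h. An unadjusted p under 0.05 was seen for 0, 0 and 2 at 2, 4 and 8 h, DESeq2 called 0 at each, and limma-voom called 8, 0 and 4. Camera gave this list adjusted p = 0.143, 0.806 and 0.703 at 2, 4 and 8 h. Without 0 h replicate 2, which is high in muscle and lipid-associated macrophage genes, camera called the list higher, with adjusted p = 1.60e-06, 1.13e-05 and 2.58e-04, and without 2 h replicate 1 at 2 h (0.0348). Its adjusted p in these fits was 0.694, 0.554, 0.711 and 0.962 with an estimated correlation. Without the 3 libraries highest in skeletal muscle genes it was called higher too (1.32e-05, 3.66e-05 and 1.58e-05), with adjusted p = 0.557, 0.4997 and 0.585 with an estimated correlation.

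Among 16 pan-macrophage genes 1 fell at 2 h over all genes, Cd14, a receptor for bacterial lipopolysaccharide, from 253 ± 39.4 to 94.5 ± 23.4 CPM, and 3 adjusted over the list alone with Aif1 and Lyz2. At 4 h 0 passed over all genes by edgeR and 3 fell adjusted over the list alone, and at 8 h 0 and 1. At 4 h and 8 h 4 and 6 pan-macrophage genes had an unadjusted p under 0.05, and DESeq2 called 2 and 2 and limma-voom 2 and 4. Camera called the pan-macrophage list lower at 2 h (adjusted p = 0.0377) and at 4 h (0.00127). The adjusted p was 0.733 and 0.533 with an estimated correlation. The call at 2 h was lost without 0 h replicate 2 (0.213), 2 h replicate 1 (0.579) or 2 h replicate 3 (0.123), and at 4 h without 4 h replicate 3 (0.0628).

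Between durations no gene passed the edgeR test. For 4 h against 2 h 0 genes passed and 851 had an unadjusted p under 0.05, and the smallest p-values belonged to Baz1a, Top1 and Nxpe5 (log2 0.52, 0.47 and 0.88, adjusted p = 0.820). DESeq2 called 54 and limma-voom 0, and edgeR called 12 without 4 h replicate 2. Neutrophil genes had 0 of 11 passing over all genes by edgeR (6 at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma-voom) and 6 higher adjusted over the list alone, with S100a8 at log2 4.01 ± 0.94 and Cxcr2 at 2.89 ± 0.73. For this list the median was 1.78, the camera adjusted p was 1.96e-04, and the adjusted p was 0.939 with an estimated correlation. Without 4 h replicate 2 the median was 2.52 and the list passed with an estimated correlation too (adjusted p = 0.00346), and without 4 h replicate 1 the median was 1.15.

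For 8 h against 4 h 0 genes passed by edgeR and 1999 had an unadjusted p under 0.05. Gbp2 stood at log2 3.92 ± 0.47 (adjusted p = 0.123), and Nrg2 and Il18bp at 3.22 ± 0.44 and 2.91 ± 0.44 (adjusted p = 0.140). DESeq2 called 479 and limma-voom 1829, and edgeR called 27 without 4 h replicate 2 and 13 without 8 h replicate 2. Interferon response genes were higher in 18 of 18, natural killer and cytotoxic cell genes in 11 of 11 and hypoxia response genes in 18 of 18. By edgeR 0 of each passed over all genes, and 4, 6 and 0 passed adjusted over the list alone. In the same order 6, 7 and 6 had an unadjusted p under 0.05, DESeq2 called 4, 5 and 1, and limma-voom called 5, 2 and 16. Camera gave these lists adjusted p = 3.26e-07, 1.79e-06 and 1.34e-07. The adjusted p of each was 0.614 with an estimated correlation. The interferon median of 1.28 was 0.86 without 8 h replicate 1.

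Neutrophil genes were lower at 8 h than at 4 h in 10 of 11, with 0 passing over all genes by edgeR (7 at an unadjusted p under 0.05, 3 by DESeq2 and 3 by limma-voom) and 6 adjusted over the list alone. S100a8 and Cxcr2 stood at log2 -3.30 ± 0.90 and -2.76 ± 0.72. The neutrophil list had a median of -1.33 and a camera adjusted p of 0.0208, with adjusted p = 0.614 with an estimated correlation. The camera call was lost without 4 h replicate 1 (0.0973, median -0.54), 4 h replicate 3 (0.113, median -0.66) or 8 h replicate 3 (0.0775). Without 4 h replicate 2 the median was -2.28, and the list passed with an estimated correlation (adjusted p = 0.0198).

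Cell cycle genes were lower at 8 h than at 4 h in 18 of 19. By edgeR 0 passed over all genes (17 at an unadjusted p under 0.05, 1 by DESeq2 and 18 by limma-voom), and adjusted over the list alone 16 were lower and 1 higher, among them Cenpf and Ccnb1 at log2 -1.44 and -1.63, and the 1 higher was Cdkn1a, an inhibitor of the cycle. The cell cycle level was 0.91 and 0.77 in 4 h replicates 1 and 3 and -0.67 in 4 h replicate 2, within the 8 h range of -0.80 to -0.51. The median of -1.12 was -0.78, -1.70 and -0.85 without 4 h replicates 1, 2 and 3, and the camera adjusted p stayed between 5.56e-10 and 5.07e-04 with each library left out in turn. Genes of multinucleated giant cells and osteoclasts were lower in 10 of 10, with 0 passing over all genes by edgeR (7 at an unadjusted p under 0.05, 5 by DESeq2 and 6 by limma-voom) and 6 adjusted over the list alone. Their median of -1.79 was -2.69 without 4 h replicate 2. Oscar and Ocstamp stood at log2 -3.66 ± 0.94 and -2.72 ± 0.68. Oscar reached 27.2 and 26.4 CPM in 4 h replicates 1 and 3 and 2.17 CPM in replicate 2. The camera adjusted p was 3.48e-06 for the cell cycle and 1.60e-05 for the giant cell list, and the adjusted p of both was 0.614 with an estimated correlation.

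For 8 h against 2 h 0 genes passed by edgeR and 1035 had an unadjusted p under 0.05, with Gbp2, Sema4a and Il18bp at log2 3.25, 1.30 and 2.83 (adjusted p = 0.274, 0.274 and 0.340). DESeq2 called 48 and limma-voom 3, and edgeR called 4 without 8 h replicate 2. Cell cycle genes were again lower in 18 of 19, with 0 passing over all genes by edgeR (17 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom) and 14 adjusted over the list alone (camera adjusted p = 6.56e-09), and 2 h replicate 1 had a level of -0.53 against 1.03 and 0.58 in 2 h replicates 2 and 3. The median of -1.09 was -0.70 without 2 h replicate 2. The adjusted p of the cell cycle list was 0.467 with an estimated correlation.

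Tested together, the 4 durations differed in 118 genes, and the smallest p-values belonged to Rab11fip1 (adjusted p = 0.00687), Nlrp3, Dgat1, Fgr and Sycp2 (adjusted p = 0.00898 each). Fgr, a kinase of myeloid cells, stood at 127 ± 8.89 CPM at 0 h and 25.8 ± 6.18, 44.4 ± 10.9 and 31.6 ± 5.71 CPM at 2, 4 and 8 h, and Sycp2 at 4.31 ± 1.11, 0.273 ± 0.0553, 0.735 ± 0.413 and 0.234 ± 0.0308 CPM. The count was 2, 220 and 4 without 0 h replicates 1, 2 and 3, 7 without 2 h replicate 3, 9, 216 and 63 without 4 h replicates 1, 2 and 3, and 9, 50 and 14 without 8 h replicates 1, 2 and 3. It was 1445 by DESeq2, 2537 by limma-voom and 39 without the 3 libraries highest in muscle genes.

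A linear slope over hours passed for 0 genes by edgeR, with 1743 at an unadjusted p under 0.05. The smallest p-values belonged to Gbp2b, C6 and Sectm1a, with slopes of log2 1.31 ± 0.18, 0.54 ± 0.08 and 0.41 ± 0.06 per hour (adjusted p = 0.115, 0.115 and 0.134). DESeq2 called 265 and limma-voom 2, and edgeR called 9 without 2 h replicate 1.

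The comparisons with 0 h share their control libraries, so their fold changes resemble each other by construction. The correlation across genes, which are not independent replicates, was 0.798 between 2 h and 4 h, 0.751 between 2 h and 8 h and 0.616 between 4 h and 8 h, against 0.507, 0.501 and 0.496 in 50 simulations of unchanged groups with shared controls. The covariances were 0.347, 0.430 and 0.279 against 0.0949, 0.0939 and 0.0932 simulated, a difference of 0.252, 0.336 and 0.185. The sign was shared by 74.6%, 75.5% and 66.8% of genes, against 66.7%, 66.5% and 66.5% simulated. The simulations drew each gene independently, while in the libraries genes such as those of muscle moved together. The simulated values may therefore understate how far such figures vary without a change, and the differences do not measure agreement beyond the shared controls.

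Of the genes called at 2 h and at 8 h, 13 higher and 71 lower genes were shared, against 0.0967 and 1.02 for independent lists of the same size, a value that leaves out the shared controls. The simulations called at most 1 gene in a comparison, so their shared counts of 0 and 0 follow from the lack of calls and give no measure for these numbers. The 3 genes called at 4 h, Nlrp3, Rab11fip1 and Dgat1, were among those called at 2 h and at 8 h. With 3 control libraries the controls could not be divided so that each part kept 2 libraries, so part of the overlap may come from the shared controls.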

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

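The comparison and the lists were planned, while the member genes named here and the tests of these lists with libraries left out were chosen after the result was seen. A test of the difference between 8 h and 4 h passed for 3 gene lists by the mixed fry test, which counts change in either direction: chemokines and cytokines (adjusted p = 0.0399), classically activated macrophage (adjusted p = 0.0326), and pyroptosis and inflammasome (adjusted p = 0.0399). The mixed test passed for 0 of 41 lists between 8 h and 2 h and for 0 between 4 h and 2 h, where camera called 19 and 11. The 3 lists share genes: Il1b is in each of them. Cxcl9, Cxcl10, Tnf, Il6 and Ccl5 are in both the chemokine and the classically activated macrophage list. The 3 calls are therefore not separate results. Members moved both ways. Cxcl9, a chemokine induced by interferon, stood at 11.5 ± 4.44 CPM at 4 h and 174 ± 112 CPM at 8 h (log2 3.92 ± 0.76, adjusted p = 0.153), and Il1b at 35.3 ± 21.5 and 2.22 ± 1.47 CPM (log2 -3.99 ± 0.78, adjusted p = 0.153). Over all genes 0 members of the 3 lists passed by edgeR, with 5, 4 and 4 at an unadjusted p under 0.05, 4, 2 and 2 by DESeq2 and 5, 4 and 3 by limma-voom. Adjusted over the list alone 4, 2 and 2 passed.

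The 3 calls rest on few libraries. Over 14 alternatives the adjusted p ran from 0.000649 to 0.593 for chemokines and cytokines, from 0.00135 to 0.524 for classically activated macrophage and from 0.0149 to 0.524 for pyroptosis and inflammasome, and 7, 6 and 7 of the alternatives lost the call. In the same order it was 0.208, 0.208 and 0.208 without 4 h replicate 1, 0.593, 0.524 and 0.524 without 4 h replicate 3, 0.391, 0.391 and 0.391 without 8 h replicate 1, and 0.168, 0.168 and 0.168 without 8 h replicate 3. It was 0.0888 for each without 2 h replicate 3 and 0.0722 for each without the 3 libraries highest in skeletal muscle genes. Without 0 h replicate 3 it was 0.0770 for the first and the third list. Groups of 3 libraries were not tested for single libraries far from the rest.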

How the results depend on the processing

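The pooled comparison, the fit without the 3 libraries highest in skeletal muscle genes, the fit with a muscle covariate, the list tests between durations with libraries left out, and the alternatives for Trib3, for Scn7a and for the mixed fry calls were chosen after the results were seen. The alternatives for Hdc were also chosen then. For single named genes under the alternatives, 2052 values stayed on the same side of the threshold, 504 lost the call and 55 gained it. Where either fit called the gene, 0 reversed direction. Direction was not compared where neither fit called it, and there some genes changed sign. Gpnmb at 8 h, for example, went from log2 -0.68 to 1.53 without 0 h replicate 2. Size factors by relative log expression and the stricter filter kept each count of genes within 1.5 times, as did the order of the durations for the slope. Where values moved, the cause was not tested. Library totals of 18248188 to 20802437 left 14890 genes above the low-count filter and 18962 with any count, so changes in rarer transcripts were not tested.

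DESeq2 called 1033, 292 and 1254 genes at 2, 4 and 8 h against 0 h, 54 at 4 h against 2 h, 479 at 8 h against 4 h, 48 at 8 h against 2 h, 1183 in the pooled comparison, 1445 among the 4 durations and 265 for the slope. limma-voom with quality weights called 2274, 210, 2561, 1829 (8 h against 4 h), 3 (8 h against 2 h), 1711 (pooled), 2537 (4 durations) and 2 (slope). With only the 2 groups compared the counts at 2, 4 and 8 h were 33, 0 and 551. Without the low-count filter 1 gene passed at 4 h. Without the 3 muscle-rich libraries 299 genes passed at 8 h and 39 among the 4 durations, and with the muscle covariate 12 at 4 h and 306 at 8 h.

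Camera with the preset correlation called 21, 20, 16 and 18 lists at 2, 4 and 8 h and in the pooled comparison, an estimated correlation 0, 0, 0 and 0 (1 list in each, neutrophil, without 4 h replicate 2), and fry 6, 3, 5 and 6. The correlation of fold changes at 2 h and 8 h, 0.751, was 0.632 without the low-count filter, 0.805 with only the 2 groups compared and 0.820 without the muscle-rich libraries.

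Leaving out 1 library at a time gave 0 to 556 genes at 2 h, 0 to 54 at 4 h and 0 to 390 at 8 h against 0 h, 0 to 12 at 4 h against 2 h, 0 to 27 at 8 h against 4 h, 0 to 4 at 8 h against 2 h, 75 to 619 pooled, 2 to 220 among the 4 durations and 0 to 9 for the slope. Lists called ran from 16 to 22, 17 to 21, 14 to 19 and 15 to 19, and the correlation from 0.607 to 0.818.

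With the replicate number as a block, 73, 0 and 16 genes passed at 2, 4 and 8 h against 0 h, 183 pooled and 38 among the 4 durations, and Trib3 and Scn7a at 8 h lost the call (0.115 and 0.0659). The numbers did not pair the libraries: 4 of 18 pairs with the same number had correlated deviations above 0.1 (range -0.56 to 0.39, median -0.03, and 0.02 for other numbers), and 1 of 12 libraries correlated best with its own number.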

Other observations

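The tests of all immune cells, of 1 library, of natural killer genes and of other splits of the libraries were chosen after their results were seen, as were the single genes named in the first 2 paragraphs. Genes of endoplasmic reticulum stress were higher than at 0 h in 14, 14 and 10 of 16 at 2, 4 and 8 h, with list levels of -0.30 at 0 h and 0.15, -0.06 and 0.20 at 2, 4 and 8 h. Trib3, a pseudokinase induced by amino acid shortage, rose at 8 h from 5.30 ± 1.92 to 32.9 ± 6.19 CPM (log2 2.63 ± 0.53, edgeR adjusted p = 0.0496, and 2.48e-05 to 0.194 over the alternatives). The Trib3 call was lost in 12 of 21 alternatives, among them no low-count filter (0.0527), the stricter filter (0.0519) and the fit without the 3 libraries highest in skeletal muscle genes (0.0580), and without 0 h replicates 1, 2 and 3 (0.194, 0.0652 and 0.113), 8 h replicates 1, 2 and 3 (0.185, 0.111 and 0.124), 2 h replicate 3 (0.0536) and 4 h replicate 1 (0.0801), and its log2 value stayed between 2.40 and 2.93. At 8 h 1 gene of the list rose over all genes tested and 3 adjusted over the list alone, and at 2 h 0 by edgeR (4 at an unadjusted p under 0.05, 3 by DESeq2 and 4 by limma-voom) and 3 adjusted over the list alone. At 4 h 0 passed by edgeR over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). Camera gave adjusted p = 0.00309, 0.0121 and 0.00955 at 2, 4 and 8 h, and the adjusted p was 0.615, 0.568 and 0.661 with an estimated correlation. These camera calls for endoplasmic reticulum stress were lost without 0 h replicate 2 (0.0778, 0.178 and 0.127), at 2 h also without 2 h replicate 1 (0.0635), at 4 h without 0 h replicate 1 (0.0682), 4 h replicate 2 (0.293) or the 3 libraries highest in skeletal muscle genes (0.0949), and at 8 h without the 3 libraries highest in skeletal muscle genes (0.107).

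Genes of the peripheral nerve and Schwann cell list were higher than at 0 h in 11, 7 and 11 of 11 at 2, 4 and 8 h, with medians of 1.03, 0.79 and 1.08, and of 0.56, 0.05 and 0.65 without 0 h replicate 1. List levels were -0.59 at 0 h and 0.40, -0.30 and 0.49 at 2, 4 and 8 h. Camera gave adjusted p = 0.00186, 0.0740 and 0.00166, and the adjusted p was 0.615, 0.651 and 0.580 with an estimated correlation. At 4 h camera called the nerve list without 0 h replicate 3 (0.0225) or 4 h replicate 3 (0.0368), with adjusted p = 0.575 and 0.720 with an estimated correlation, and the median was 0.27 without 4 h replicate 2. Scn7a, a sodium channel gene, rose at 8 h by log2 1.46 ± 0.23 (adjusted p = 0.0316, and 7.52e-07 to 0.147 over the alternatives), the 1 gene of the list to pass over all genes and adjusted over the list alone. The Scn7a call at 8 h was lost in 8 of 21 alternatives, among them without 0 h replicates 1 and 3 (0.134 and 0.0961), 8 h replicates 1, 2 and 3 (0.147, 0.0812 and 0.0748), 2 h replicate 3 (0.0502) and 4 h replicate 1 (0.0581). Between 4 h and 8 h the mast cell genes Mcpt4 and Cpa3 stood at log2 2.61 ± 0.66 and 2.95 ± 0.78, 2 of the 4 genes of 10 that passed adjusted over the list alone. Over all genes 0 of the 10 passed by edgeR, with 5 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom. The level of this list was 0.40 at 0 h and -0.23, -0.52 and 0.34 at 2, 4 and 8 h, lowest at 4 h. Against 0 h 1 gene of the list passed at 2 h and at 8 h, Hdc. It stood at log2 -5.70 and -4.73 (edgeR adjusted p = 0.0300 and 0.0476). The Hdc call was lost in 11 of 21 alternatives at each duration (adjusted p up to 0.134 and 0.197).

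Neutrophil genes were lower in the ischemia groups than at 0 h. Here and below a spread is a standard error over the genes of a set, as is the ± of the clock genes. Genes that move together are not replicates, so it does not measure variation between libraries. Over libraries the pan-macrophage level ran from -0.55 in 2 h replicate 1 to 0.44 in 8 h replicate 1. A lower share of all immune cells as the whole cause would need the pan-macrophage list near -1 or below, and its median was 0.015 with a spread of 0.14, though T cell levels (0.70 at 0 h against -0.18, -0.39 and -0.12) and lymph node stroma levels (1.37 against -0.70, -0.59 and -0.08) were lower too, so a smaller share of lymphoid tissue stays open. Muscle in some libraries would need the neutrophil median to shrink with the muscle covariate, and it was -3.43 with a spread of 0.45. For another time of day at collection, the bound set was that clock genes of opposite phase part by 1 or more. They parted by 0.64 ± 0.29 (10 and 4 genes, means of 0.46 and -0.18). That is under the bound, but the means have opposite signs, so a smaller shift in time stays open. Of 14 clock genes 0 passed by edgeR at 2, 4 or 8 h against 0 h. DESeq2 called 1, 0 and 1 and limma-voom 4, 0 and 6. A list of sex-linked genes was fixed beforehand as a check of animal sex, and 4 of its genes were tested. At 2 h against 0 h 1 passed by each of edgeR, DESeq2 and limma-voom. At 4 h and at 8 h 0 passed, with 1 at an unadjusted p under 0.05 in each. Animal sex was not tested further. None of these tests decides whether ischemia itself lowers neutrophil content, and the handling of the 0 h grafts was not tested apart from it.

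Interferon response genes were higher at 8 h than at 0 h. With 8 h replicate 1 left out the median on the scale of edgeR was 1.16 with a spread of 0.18. That is above the 0.5 set as the bound, which argues against that 1 library as the whole cause. The median of 1.76 with all libraries is on the scale of limma, so the size of the change is not given by these values. Levels of the interferon and natural killer lists went together within the groups (r = 0.898, exact permutation p = 0.0108, two-sided over 1296 orders, 1 relation tested). Over 12 libraries Pearson r was 0.898 (permutation p = 0.00016) and Spearman rho 0.853 (permutation p = 0.00073), and r was 0.783 without 8 h replicate 1 and 2 h replicate 2. A larger share of cytotoxic cells, whose Gzma stood at 2.27 ± 0.370 CPM at 0 h and 18.7 ± 15.3 CPM at 8 h, may accompany the interferon response, and the duration of ischemia itself stays open.

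Skeletal muscle genes were high in 3 libraries of different groups. Among 17 mature muscle genes outside the fixed list the median log2 ratio of these 3 libraries to the other 9 was 3.01 with a spread of 0.33, and 15 genes were above 2, while Eno3 and Cox6a2 stood at 0.40 and 0.75. That falls just short of the share set beforehand, so mature muscle in the dissected tissue could be the source and stays open. The 7 genes of newly forming fibres had a median of -0.12 with a spread of 0.07, but 5 of them were under 1 CPM in both sets of libraries, near the floor, so regenerating fibres stay open too.

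Other splits of the libraries were counted for each result. For the pooled comparison 1 of 100 splits gave as many genes, the real one with 375, and the highest other had 86. That share of 0.01 has a 95% interval of 2.53e-04 to 0.0545, which counts the real grouping as a draw and so leans high. The comparison was added after the data were seen, so chance is not firmly excluded. The draws held 85 distinct sets of 3 libraries in place of the 0 h group. For the 4 durations 4 of 100 splits gave 118 genes or more and the highest other had 2398. That share of 0.04, with the real grouping counted likewise, has a 95% interval of 0.0110 to 0.0993, so chance is not firmly excluded there either. A split with 2398 genes points to a structure of the samples beside the groups. For the slope the real count was 0 (by edgeR, with 1743 at an unadjusted p under 0.05, 265 by DESeq2 and 2 by limma-voom), so 100 of 100 splits give as many by construction and nothing is tested. The highest other had 1863, which also points to such a structure.

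Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. At 2 h against 0 h the real count was 173 and the highest other 531 (2 splits as large), which points to a structure of the samples. At 4 h it was 3 and 3 (2 splits), and at 8 h 162 and 0 (1 split). At 4 h against 2 h, 8 h against 4 h and 8 h against 2 h the real count was 0, so 10 of 10 splits give as many by construction and nothing is tested, and the highest other counts were 116, 0 and 0. The counts of 0 are by edgeR, with 851, 1999 and 1035 genes at an unadjusted p under 0.05, 54, 479 and 48 by DESeq2 and 0, 1829 and 3 by limma-voom.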
